A study of Mus musculus with 4 samples.

How the data were processed

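The files hold 2 joint 10x libraries, 1 per genotype, each with a matrix of RNA and chromatin values for the same barcodes. Per the file headers, the matrices were made with Cell Ranger ARC 2.0.1, and per the submitters' processing notes Seurat 4.1.0 and Signac 1.6.0 were also used, with no step named. The values are raw counts as deposited: UMIs for 31053 genes and transposition counts for peaks, with no normalisation. How barcodes were called as cells is not stated. The notes name GRCm39 and GRCm38 with no role. Gene starts in the files equal those of GRCm38 in the RefSeq gene table, so coordinates are given in that build, counted from 1. Of the gene features, 30934 matched a current symbol. Only gene extents were at hand, and exon structure was not used here.

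Nuclei were kept with 500 to 25000 UMIs, at least 300 genes, 1000 to 100000 peak counts and a mitochondrial share under 20%. At or over that mitochondrial limit were 8407 control barcodes and 4365 of the library labelled CKO. Scrublet, run in scanpy 1.11.5 per library with an expected rate of 0.08, called 12 control nuclei and 0 of the library labelled CKO as doublets, far under that rate, so doublets were in effect not removed. Both libraries were clustered together on RNA without integration (2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 0.6, with leidenalg 0.10.2 and igraph 0.11.9). Clusters were named from 16 marker lists by the highest mean log2 fold over the other clusters, with at least 3 detected markers and a score of at least 0.3. Clusters named for activated AT2 cells would count as AT2-like, but no cluster of the main setting took that name.

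UMIs were summed per library over alveolar epithelial nuclei, or over a class with at least 100 nuclei in each library, as CPM of nuclear-encoded UMIs. Log2 ratios carry exact conditional-binomial 95% intervals, shares Clopper-Pearson intervals and single counts Poisson intervals. Such intervals, and the floor of 3 counts, say nothing of variation between mice. With 1 library per genotype no p-value or count of changed genes is given. For 30 gene lists the median log2 ratio of members with at least 20 UMIs was placed among 10000 random lists of the same size matched on mean expression in 20 bins, and a list was called apart under the 2.5th or over the 97.5th percentile. This describes these 2 libraries.

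The rule for named genes was fixed before the data were examined. It takes the 12 highest and 12 lowest genes in alveolar nuclei by the interval bound nearest 0 (at least 200 UMIs, gene models without a name and mitochondrial genes left out), and 6 and 6 within each class (at least 100 UMIs). It adds the 2 highest and 2 lowest members of each list that stands apart, and always Ptgir, Jun, Trp53, Cdkn1a, Mdm2, Sftpc, Krt8, Hopx and Ager. Other genes named (Jund, Fos, Fosl1, Sftpb, Gm42418, AY036118 and Wrap53) were chosen after their values were seen. For chromatin, shared regions are those where peaks of both libraries overlap. Each library's counts were summed over its own peaks within them, and scaled to the library's total in those regions. The width counted in a region can thus differ between libraries. A promoter region lies within 1000 bases of a gene start. The 6 highest and 6 lowest regions with at least 200 counts are named.

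On simulated counts for 9351 genes with 200 changed genes, all 68 genes changed 1.5-fold, 68 changed 2-fold and 64 changed 4-fold had the right direction. The intervals held the true value for 97.1%, 100% and 93.8% of them and for 95.4% of unchanged genes. Of 200 unchanged lists of 12 genes, 5 stood apart, and all 200 lists changed 1.5-fold did. Unchanged genes were simulated at the same Poisson rate in both libraries, so this checks the calculation under counting error alone. Ratios of real genes spread more widely and genes of a list can move together, so these rates do not carry over to the data.

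Alternatives set in advance numbered 40 (filters, doublets, clustering, scaling, weights, depth, class makeup, minimum counts, overlap and regions), and 9 were added after seeing the data. Motif accessibility was planned but not analysed here, since no genome sequence was at hand. A classing of nuclei by chromatin alone was revised after a first version had been seen, because its threshold was set on the nuclei that built the class profiles. Further tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.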

Results

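Joint nuclear RNA and open chromatin profiles (10x multiome, in which RNA molecules and transposition events are counted in the same nucleus) were collected from lineage-labelled alveolar type 2 (AT2) cells of male mouse lung, 8 days after bleomycin, a drug that injures the alveolar epithelium. AT2 cells make surfactant and give rise to the flat alveolar type 1 (AT1) cells after injury. The control genotype carried a tamoxifen-inducible Cre at Sftpc, the surfactant protein C gene, with a membrane reporter that turns green in recombined cells. The CKO genotype also carried a floxed gene for IP, the prostaglandin I2 receptor encoded by Ptgir. The 4 samples are the RNA and chromatin parts of 2 joint libraries, 1 per genotype, so no difference below has a replicate check and none was tested. The control library held 13569 barcodes with 48378328 UMIs (counted RNA molecules) and 47307986 peak counts, and the library labelled CKO held 10925 barcodes with 30818808 UMIs and 37365247 peak counts. Median UMIs per deposited barcode were 2603 and 2280, and the median mitochondrial share of UMIs was 24.2% and 16.6%. After filtering, 2173 nuclei were kept in the control library and 3883 in the library labelled CKO. Intervals are 95% intervals that cover counting error only.

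Ptgir, the gene removed in the CKO genotype, was almost undetected in both libraries. In alveolar epithelial nuclei it had 0 UMIs of 5989947 in the control library, where a floor of 3 counts is 0.501 CPM (counts scaled to the nuclear-encoded UMIs of the nuclei compared) and the Poisson upper bound 0.616 CPM, and 2 UMIs in the library labelled CKO. Over all deposited barcodes it had 2 UMIs in the control library and 10 in the library labelled CKO, a 7.09-fold higher rate there (interval 1.51 to 66.5). Read alone, that direction goes against the label. However, non-alveolar nuclei, which a Cre at Sftpc is not meant to reach, made up more of that library, so it does not decide the label. In kept nuclei the ratio was 3.65 (0.443 to 168, from 1 and 6 UMIs), and in non-alveolar kept nuclei, which held 4 of those 6 UMIs, it was 0.426 (0.0421 to 21.0), so the direction was not fixed once nuclei were filtered. The labels do not say which exon was removed, and a 3' tag outside it checks nothing, so "the library labelled CKO" is used throughout and every direction below rests on the label alone. At the Ptgir gene (GRCm38, chromosome 7, 16906490 to 16910905), peak counts in alveolar nuclei were 10 in the control library and 6 in the library labelled CKO. In all kept nuclei they were 13 and 60.

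The first comparison asks which alveolar cell states each library held, since the series title speaks of alveolar regeneration. Nuclei named transitional-like (by a marker list of the state between AT2 and AT1) or AT1-like made up 47.8% of alveolar epithelial nuclei in the library labelled CKO (1129 of 2364, Clopper-Pearson interval 45.7 to 49.8) and 25.6% in the control library (526 of 2053, 23.7 to 27.6). Both shares were lower with no filter on nuclei and without the mitochondrial limit, with the same direction. AT2-like nuclei made up 51.6% (49.5 to 53.6) against 72.8% (70.8 to 74.7). Transitional-like nuclei were 28.1% against 16.7%, AT1-like nuclei 19.6% against 8.91%, and cycling nuclei 0.677% against 1.56%. The boundary between the transitional-like and AT1-like classes moved between clustering settings, and with doublets kept the AT1-like direction turned (7.77% in the library labelled CKO and 9.46% in control), so their sum carries the comparison. Krt8 itself was not highest in transitional-like nuclei (234 CPM in the control library and 315 in the library labelled CKO, against 264 and 267 in AT2-like and 294 and 535 in AT1-like nuclei). The AT1-like cluster also scored higher on the whole transitional marker list (1.31) than the transitional-like cluster did (1.04), so that list does not set the 2 classes apart. AT2-like nuclei of the 2 libraries lay mostly in different clusters, with 1183 of the 1219 from the library labelled CKO in 1 cluster that held 63 control nuclei. Another AT2-like cluster held 815 control nuclei and 25 of the library labelled CKO. Its control nuclei were shallow (median 1263 UMIs, against 3478 in the AT2-like cluster with 617 control nuclei). The ribosomal RNA-like genes AY036118 and Gm42418 were among its leading genes. Shares without that cluster were not computed. It held 815 of the 2053 control alveolar nuclei and 25 of the 2364 of the library labelled CKO. Leaving it out would therefore raise the control share far more than the other and narrow the gap between them. Alveolar epithelial nuclei made up 60.9% of kept nuclei in the library labelled CKO (59.3 to 62.4) and 94.5% in the control library (93.4 to 95.4), the others being mainly immune cell types.

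**Figure D1:**
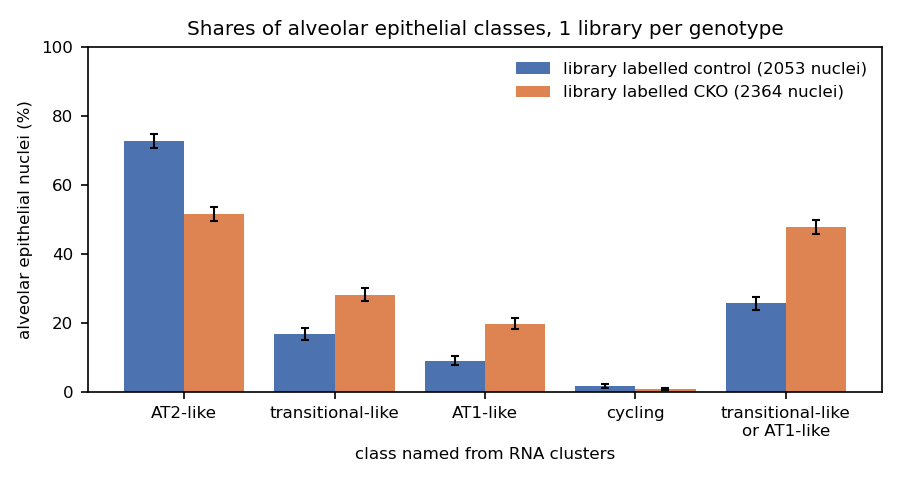
Bars give the percent of alveolar epithelial nuclei in each class named from RNA clusters, for the 2053 nuclei of the library labelled control and the 2364 of the library labelled CKO, with exact 95% intervals for counting error. Transitional-like or AT1-like nuclei together made up 25.6% and 47.8%, and both shares were lower with no filter on nuclei. The AT2-like bars include a shallow cluster of 815 control nuclei and 25 of the library labelled CKO, on which the gap partly rests.

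The second comparison asks which genes differed in alveolar epithelial nuclei, and in particular Jun and the p53 pathway, which the series title names. RNA of the AP-1 subunits, the transcription factor family of Jun, was lower in the library labelled CKO. Jun was at 710 CPM in the control library and 323 in the library labelled CKO (log2 ratio -1.14, interval -1.21 to -1.06). Fosb (-1.55) and Junb (-1.21) were lower as well, as were Jund (584 and 292 CPM) and Fosl1 (27.0 and 13.6 CPM). Of 10 measured subunits 7 were lower, and Batf (1.67, from 11 and 40 UMIs), Fosl2 (0.24, but -0.20 under median-of-ratios scaling) and Fos (0.034, interval -0.048 to 0.12) were not. The list's median log2 ratio was -0.75, at percentile 0 of 10000 expression-matched random lists. Within the classes the median was -0.70 in AT2-like, -0.40 in transitional-like and -0.78 in AT1-like nuclei, each under the 2.5th percentile. The same subunits, summed without a filter on nuclei, had a log2 ratio of -0.86 in alveolar nuclei, -0.88 (-0.97 to -0.79) in T and NK cell-like nuclei and -0.52 (-0.57 to -0.46) in macrophage and monocyte-like nuclei of the same libraries. Droplets of both these cell types also held Sftpb, a surfactant gene, at 2480 CPM in the control library and 1921 in the library labelled CKO for T and NK cells, and at 2556 and 1730 for macrophages and monocytes. Alveolar nuclei, also without a filter, held Sftpb at 3842 and 4119 CPM.

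Immediate early genes, which respond within minutes to stimuli and to tissue dissociation, were lower too, with a median of -0.48 at percentile 0 and 12 of 18 members lower. Summed without a filter on nuclei, they were lower in T and NK cell-like nuclei (-0.44, -0.53 to -0.35) and in macrophage and monocyte-like nuclei (-0.19, -0.24 to -0.14) as well as in alveolar nuclei (-0.38). Egr1 was the most reduced of them (528 and 69.2 CPM, -2.93, interval -3.07 to -2.79), followed by Ier2 (-1.40), while Hspa1b (1.32) and the phosphatase gene Dusp1 (0.69) were higher.

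No difference in Trp53 RNA, which encodes p53, was detectable at this depth (23.0 and 24.5 CPM, log2 ratio 0.088, interval -0.25 to 0.42). The p53 targets had a median of 0.60 at percentile 96.4, inside the central range of random lists, with 20 of 24 members higher and 15 above the all-gene median. The list stood apart as higher without the mitochondrial limit on nuclei (percentile 99.6) and with no filter on nuclei (99.98), and was not apart in the other 12 of 14 alternatives. Within the classes it was not apart, with medians of 0.32 in AT2-like (percentile 18.5), 0.40 in transitional-like (97.0) and 0.22 in AT1-like nuclei (50.7). In AT2-like nuclei 13 of 23 members lay below the gene median. Among the p53 targets over all alveolar nuclei, Cdkn1a, a cell cycle inhibitor, had a log2 ratio of 0.22 and Mdm2, which directs p53 to degradation, 0.31, both below the all-gene median. Both turned negative under median-of-ratios scaling (-0.22 and -0.13), and Mdm2 did so when control nuclei were weighted to the other library's class makeup (-0.10). In AT1-like nuclei Mdm2 was lower in the library labelled CKO (-0.97, interval -1.17 to -0.77).

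The median gene with at least 100 UMIs had a log2 ratio of 0.44 in CPM, and 0 by construction under median of ratios, so single genes are to be read against that shift. Gm42418, a locus that collects ribosomal RNA reads, took 13.3% of nuclear-encoded UMIs of alveolar nuclei in the control library and 6.09% in the library labelled CKO.

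Epithelial identity genes were higher in the library labelled CKO. AT1 identity genes had a median of 0.79 (percentile 99.98, 17 of 20 higher), led by Emp2 (1.28) and Hopx (18.9 and 63.7 CPM, 1.76, interval 1.45 to 2.07). The AT1 identity call ended when control nuclei were weighted to the other library's class makeup (0.40, percentile 95.5), and within AT1-like nuclei the list was not apart (0.18, percentile 84.9, 10 of 18 members below the gene median). Within AT2-like and transitional-like nuclei it was apart as higher (0.74, percentile 99.72, and 0.52, percentile 99.5). Ager was also higher (0.64, but -0.040 without the mitochondrial limit), and Rtkn2 was lower (-0.52, but 0.21 without that limit). AT2 identity genes had a median of 0.42, below the all-gene median of 0.47 but at percentile 99.6 among lists of like expression. Slc34a2 (1.10), Sftpd (0.60, but -0.019 without the mitochondrial limit) and Sftpc (81.6 and 119 CPM, 0.54, interval 0.38 to 0.70) were higher, while Hc (-0.79) and Napsa (-0.35) were lower. The AT2 identity call ended with no filter on nuclei (percentile 22.6) and without the mitochondrial limit (11.4). AT2 identity genes were higher within AT1-like nuclei as well (0.97, percentile 100), where Slc34a2 reached 1.99. Slc34a2 stood at 582 CPM in the non-alveolar nuclei of the library labelled CKO. Krt8, the keratin of the transitional state, had a log2 ratio of 0.43 (-0.014 under median of ratios), and the transitional list was not apart (0.47, percentile 91.4).

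Cytosolic ribosomal protein genes had a median of 1.13 (percentile 100), with Rps29 at 1.90 and Rps27 at 1.76, and both stood as high in non-alveolar nuclei of the library labelled CKO (463 and 397 CPM). Rpl10 was lowest at 0.40 (-0.038 under median of ratios). Oxidative phosphorylation genes had a median of 0.67 (percentile 99.0), led by Uqcrfs1 (1.48) and Atp5g3 (1.41), with Ndufa13 at -0.12 and Cox6a2 at -0.20. That list was at percentile 0 with no filter on nuclei and without the mitochondrial limit.

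Inflammatory and antigen presentation genes were among the lower lists. NF-kB genes had a median of -0.22 (percentile 0.14), with Cxcl1, a neutrophil attractant, at -3.17 and Tnfaip3, an inhibitor of the pathway, at -1.79, while Il33 (0.85) and Ccl20 (2.56, from 4 and 27 UMIs) were higher. Within the classes the NF-kB list was lower in AT2-like (-0.62, percentile 0) and transitional-like nuclei (-0.080, percentile 1.80) but not apart in AT1-like nuclei (0.053, percentile 26.1). MHC class II genes had a median of -0.38 (percentile 0.07), with H2-Eb1 at -1.02, H2-Ab1 at -0.88, Ciita at -0.075 and H2-DMb1 at 0.39 (-0.057 under median of ratios). That list was lower in AT2-like (-0.55, percentile 0.01) and AT1-like nuclei (-0.47, percentile 0.15), and not apart in transitional-like nuclei (0.47, percentile 69.9, 5 of 6 members higher). Interferon genes had a median of 0.10 (percentile 0.63), with Stat2 at -0.52 and Rnf213 at -0.19, and with Ifit2 (2.17, from 6 and 31 UMIs) and Gbp2 (1.34) higher.

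Genes of prostaglandin synthesis and reception, and cAMP and CREB responsive genes, which lie downstream of IP, were lower relative to like lists, but not in every alternative. Prostaglandin genes had a median of -0.015 (percentile 1.55), with Ptgs2, the inducible cyclooxygenase, at -1.56 and the transporter gene Slco2a1 at -0.24, while Ptges (0.62) and Hpgds (2.05, from 4 and 19 UMIs) were higher. The cAMP and CREB responsive list had a median of -0.075 (percentile 0.73), with Nr4a3 at -1.82 and Ppargc1a at -1.57 against Per1 (0.85) and Dusp1 (0.69). The prostaglandin call held in only 6 of 14 alternatives (percentiles 0.69 to 11.5) and the cAMP call in 9 of 14 (0.05 to 21.3). Within the classes both lists were apart as lower in AT2-like nuclei only (prostaglandin -0.14, percentile 1.83, and cAMP -0.23, percentile 0.08). In transitional-like and AT1-like nuclei the prostaglandin list was at percentiles 7.2 and 19.8. There the cAMP list had medians of 0.20 and 0.19 (percentiles 44.9 and 52).

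Lipid synthesis genes had a median of 0.0036 (percentile 1.56), with Acoxl at -1.69 and Acaca at -0.48 and with Plin2, a lipid droplet coat gene, at 1.82 and Fasn at 0.73. DNA replication genes had a median of 0.036 (percentile 0.46), with Cdc6 at -1.61, Hells at -0.80, Mcm2 at 1.25 and Gins2 at 1.00. Mitosis genes had a median of -0.17 (percentile 0.08), with Cenpe at -0.82 from 57 and 37 UMIs (0.22 under the other library's class makeup), and with Ube2c at -0.78, Cdk1 at 0.67 and Top2a at 0.23, all 3 with intervals that hold 0. The calls of these 3 lists also ended under some settings (percentiles up to 20.8, 7.05 and 30.6).

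**Figure D2:**
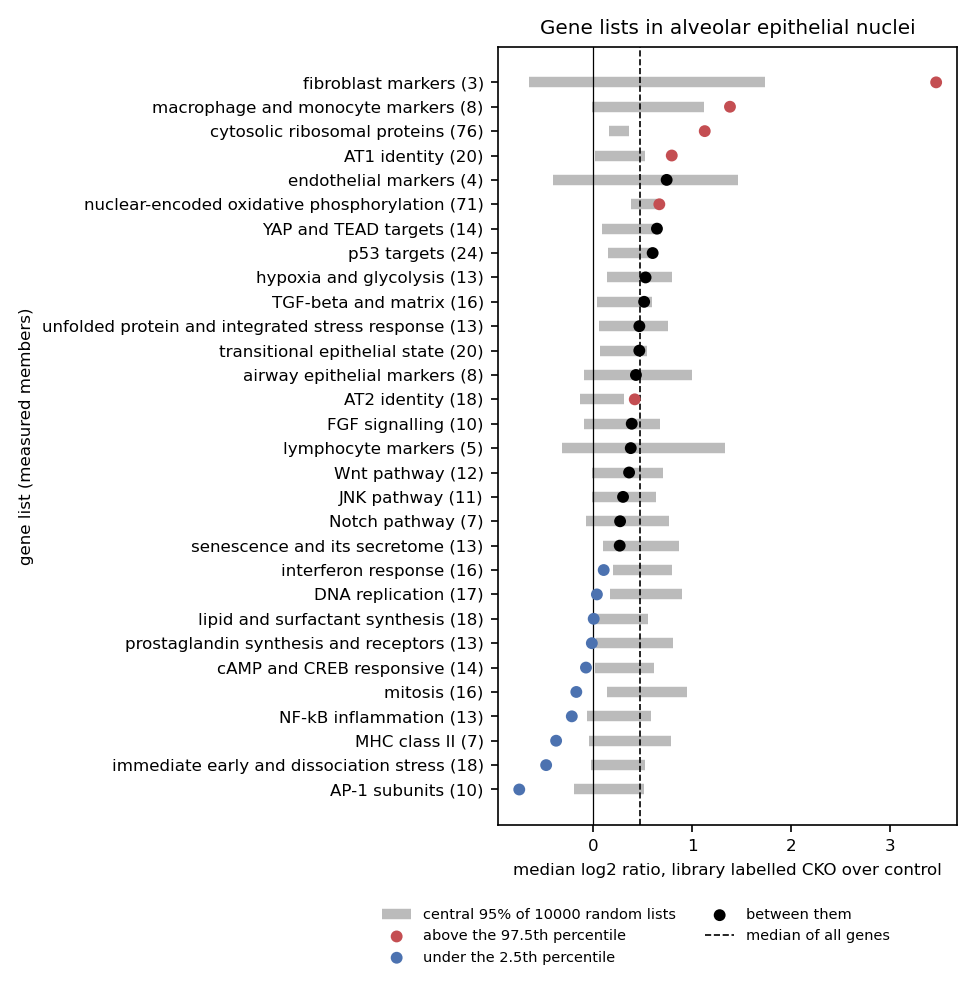
Each point is the median log2 ratio (library labelled CKO over control) of the measured genes of a list in alveolar epithelial nuclei, with the number of measured members beside the list name. Grey bars hold the central 95% of 10000 random lists matched on expression, and AP-1 subunits lie lowest at -0.75.

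The genes with the largest single differences in alveolar nuclei included markers of other cell types. The neutrophil genes S100a9 and S100a8 had 0 UMIs in the control library and 391 and 224 in the library labelled CKO, at least 114-fold and 65.2-fold higher against a floor of 3 counts over the library. Both were higher still in non-alveolar nuclei of that library (340 and 205 CPM, against 57.0 and 32.7 in alveolar nuclei). The macrophage-associated genes Chil3 (3.74), Srgn (3.19) and Spp1 (2.84) and the mesenchymal gene Vim (3.64) were also above alveolar level in those nuclei. Rgcc (206 and 828 CPM, 2.01), the cytochrome gene Cyp2b10 (2.53), Hif3a (2.87), Tinagl1 (2.30) and Msln (2.43) were higher in alveolar nuclei than in the other nuclei, and the glucocorticoid-induced gene Fkbp5 (2.55) was not. The lowest genes were Tmprss7 (84.8 and 3.06 CPM, -4.79, interval -5.50 to -4.16), Olfr170 (-4.46), Ttc23l (-3.74), Tagln3 (-3.34), Ankrd37 (-3.33), Lsmem1 (-3.19), Cxcl1, Egr1, Fbxl8 (-2.74), Necab2 (-2.62), Cc2d2b (-2.61) and Fam71a (-2.53).

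Within AT2-like nuclei the highest were S100a9, S100a8, Vim, Chil3, Hif3a (3.16) and Cyp2b10 (3.06), and the lowest Tmprss7 (-6.34), Olfr170, Tagln3, Ttc23l, Cxcl1 and Lsmem1. In transitional-like nuclei S100a9, Retnla (2.68), Selenbp1 (2.15), the club cell gene Scgb1a1 (2.07), Txnip (1.97) and Rps29 (1.79) were highest, and Egr1 (-2.33), Polg2 (-2.13), Cmss1 (-1.79), Gdf15 (-1.60), Fosb (-1.48) and Cdk8 (-1.45) lowest. Gdf15 is a p53 target. In AT1-like nuclei S100a9, Dlgap2 (3.27), Atp6v0a4 (3.01), Fkbp5 (2.80), Scgb1a1 (2.23) and Slc34a2 were highest, and Egr1 (-2.24), Gria3 (-2.17), the AT1 gene Rtkn2 (-2.06), Pdzd2 (-2.04), Gpc5 (-1.96) and Grip1 (-1.95) lowest. Scgb1a1 stood at 1339 CPM in the non-alveolar nuclei of the library labelled CKO.

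**Figure D3:**
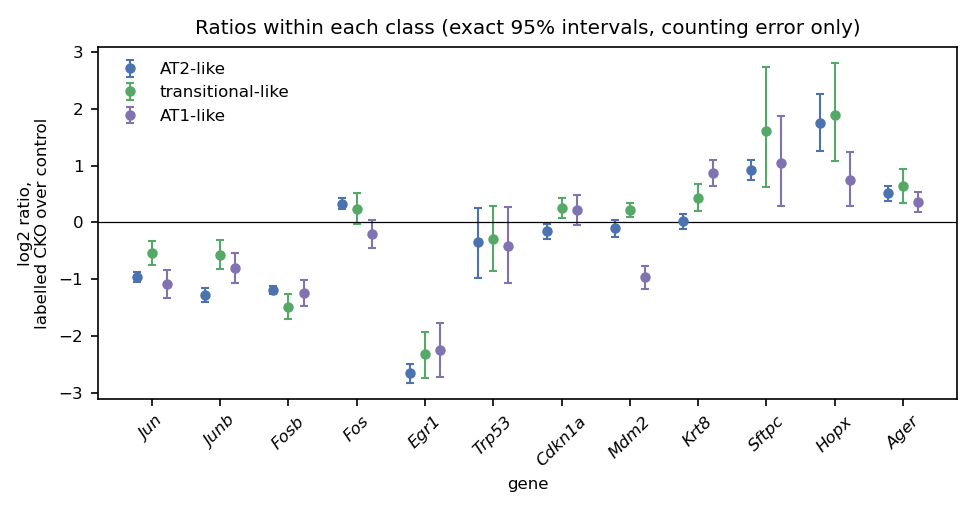
Points are log2 ratios (library labelled CKO over control) with exact 95% intervals for counting error, for 12 genes in each of 3 alveolar classes, of which Junb, Fos, Fosb and Egr1 were plotted for their list and the others are named throughout. Jun was at -0.96 in AT2-like, -0.54 in transitional-like and -1.09 in AT1-like nuclei. Read against 0, Cdkn1a (-0.16, 0.25 and 0.22), Mdm2 (-0.10, 0.22 and -0.97) and Fos (0.33, 0.24 and -0.21) differed in sign between classes, which was not tested. All of these values lay below the all-gene median of their class (0.45, 0.29 and 0.26). Intervals held 0 for Cdkn1a in AT1-like, for Mdm2 in AT2-like and for Fos in transitional-like and AT1-like nuclei.

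Markers of other cell types moved with the library. Macrophage and monocyte markers had a median of 1.38 in alveolar nuclei (percentile 99.87), with Marco (4.05, from 1 and 19 UMIs) and Ptprc (1.74) higher and Csf1r (-1.37) and Cx3cr1 (-1.13) lower. That call ended in 3 of 14 alternatives (percentile 42.7 under the stricter filter, 33.6 with nuclei weighted equally and 31.4 after thinning), and within AT2-like nuclei the list was lower relative to like lists (-0.19, percentile 2.34, from 5 genes). Of the fibroblast markers 3 were measured (median 3.47, percentile 99.99, but 96.5 without the top 8% of doublet scores), with Col3a1 at 4.97 from 1 and 36 UMIs, Col1a2 at 3.47 from 3 and 38, and Col1a1 at 1.54 from 12 and 40. Some lists that were not apart became so under alternatives. Endothelial markers (percentile 66.5) stayed inside the central range in 8 of 13 and reached 99.98, airway markers (40.6) in 10 of 14 and reached 99.95, and TGF-beta and matrix (92.6) in 11 of 14 and reached 99.78. YAP and TEAD targets (94.9) stayed inside in 11 of 14 and ranged from 1.55 to 100. The lists that were not apart in any alternative were lymphocyte markers (34.7), JNK pathway (47.8), senescence (10.8), the unfolded protein response (64.8), Wnt (53.9), Notch (36.7), FGF (69.2) and hypoxia (64.6).

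The third comparison asks where chromatin accessibility differed. The control library had 116075 peaks and the library labelled CKO 125793, of which 84.7% and 78.2% overlapped a peak of the other. Values come from 97973 shared regions, which covered 108 counts per kilobase in the control library and 130 in the library labelled CKO. Among 44366 regions with at least 100 counts the median log2 ratio in alveolar nuclei was 0.055 (quartiles -0.25 and 0.40), with -0.080 at promoters (0.047 when scaled to promoter counts) and 0.16 elsewhere. The promoter of Jun (chromosome 4, 95051889 to 95052805) was less accessible in the library labelled CKO (-0.46, interval -0.59 to -0.34). The region shared by the promoters of Trp53 and its neighbour Wrap53 (0.40, interval 0.18 to 0.61) and the promoter of Cdkn1a (0.37, 0.18 to 0.55) were more accessible. The promoter of Ager was at -0.35 (interval -0.68 to -0.019), but its interval held 0 when scaled to promoter counts (-0.22, -0.55 to 0.11). Those of Mdm2 (-0.14), Sftpc (-0.28), Krt8 (0.095) and Hopx (-0.18) had intervals that hold 0, which ended for Krt8 when scaled to promoter counts (0.22), for Sftpc under median of ratios (-0.34) and for Hopx within AT2-like nuclei (-0.47). Ptgir had no shared promoter region.

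Over gene lists, AP-1 promoters (median -0.19, percentile 59.1) and immediate early promoters (percentile 60.1) were not apart from promoters of like accessibility. Promoters of p53 targets (-0.33, percentile 1.05), AT2 identity (1.58), AT1 identity (1.10), hypoxia (1.37) and prostaglandin genes (-0.49, percentile 0.12) were lower in the library labelled CKO. Promoters of ribosomal protein (percentile 100), oxidative phosphorylation (99.99) and FGF genes (97.99) were higher. Within the classes AT2 identity promoters were not apart (percentile 20.5 over 16 regions in AT2-like, 30.3 over 8 in transitional-like and 30.9 over 7 in AT1-like nuclei). AT1 identity promoters were lower in AT2-like nuclei (percentile 0.31, 16 regions), and the 4 and 3 regions measured in transitional-like and AT1-like nuclei are too few to compare.

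The most increased regions lay 36617 bases from Csf2ra on chromosome 19 (2.21), 7032 bases from Dhx37 (1.90), over Gm45805 (1.87), 8127 bases from Gm11335 (1.85), 208 bases from Kcna7 (1.83) and 495 bases from Ctsh (1.78). Peak bases counted in control and in the library labelled CKO differed near Dhx37 (459 and 934), Csf2ra (634 and 835) and Gm11335 (571 and 713), so width can add to those ratios. They were closer at Gm45805 (897 and 931), Kcna7 (863 and 931) and Ctsh (895 and 904). The most reduced lay 430773 bases from Setbp1 on chromosome 18 (-4.07), within Chsy1 (chromosome 7, 66145663 to 66146624, -3.37), 1523 bases from Gm17508 (-3.16), over the mitochondrial gene ND4 (-3.04, from 23895 and 3509 counts), 24515 bases from Col19a1 on chromosome 1 (-2.96) and within Usp6nl (-2.49). The ND4 region lies in mitochondrial DNA, which the rule for regions did not leave out. The ND4 ratio is therefore not a difference in nuclear chromatin, and the mitochondrial share of UMIs was also higher in control barcodes. The region near Col19a1 resembled ND4, with a like ratio (-2.96) and the most counts after it among the reduced regions (7051 and 1093). Whether its counts come from mitochondrial DNA was not tested, so its ratio cannot be read as a loss of nuclear accessibility.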

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

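The tests of class shares, of class makeup, of UMIs per nucleus and both tests of chromatin-only classing were chosen after the results were seen; the tests of T and NK cell-like nuclei for AP-1 and of AT2 promoters were written before, and the macrophage value and the AT2-like promoter value were weighed afterwards. Cell types that a sort for green AT2-lineage cells would remove were present in both libraries and were more frequent in the library labelled CKO. Neutrophil-like nuclei made up 12.1% of its kept nuclei, against 0.0920% (2 nuclei) in the control library. T and NK cell-like nuclei made up 8.78% against 2.58%. Macrophage and monocyte-like nuclei made up 8.29% against 0.920%. Endothelial-like nuclei made up 3.14% against 0.552%. B cell-like nuclei made up 1.57% against 0.598%, fibroblast-like nuclei 1.47% against 0.322%, ciliated-like nuclei 1.49% against 0.138%, and nuclei of unnamed clusters 2.29% against 0.322%.

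AP-1 subunits were lower in alveolar nuclei of the library labelled CKO. Different class shares do not account for it, since the median stayed at -0.58 and at percentile 0.01 with control nuclei weighted to the other makeup, nor do UMIs per nucleus, since it was -0.92 and at percentile 0 after thinning to 1000 UMIs. Handling of the whole suspension, which would reach every cell type, met the criterion written before. T and NK cell-like nuclei showed a log2 ratio of -0.88 (-0.97 to -0.79), an interval that holds the -0.86 of alveolar nuclei. Macrophage and monocyte-like nuclei, weighed afterwards, were also lower in the library labelled CKO but less so (-0.52, -0.57 to -0.46). Handling is therefore left open. Epithelial RNA in the droplets, shown by Sftpb at 2480 and 1921 CPM in T and NK cell-like and at 2556 and 1730 CPM in macrophage and monocyte-like nuclei, weakens both values. Alveolar nuclei held Sftpb at 3842 and 4119 CPM. A large and unmeasured part of both AP-1 values can therefore be alveolar RNA, and neither value shows what those cells themselves expressed. An effect of the genotype stays open and untested.

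Transitional-like or AT1-like nuclei had a larger share in the library labelled CKO, and unequal loss to the mitochondrial limit does not account for it, as the share without that limit was 35.8% against 17.1% in the control library. Under the main filter the size of the gap rests in part on 1 shallow AT2-like cluster, with 815 control nuclei and 25 of the library labelled CKO. With nuclei classed by chromatin alone over 20 splits, the median share was 42.9% against 38.02% in held-out control nuclei, and the intervals separated in 9 splits (19 after thinning to 1000 counts). With the first version's threshold they separated in 15 splits as counted and in 1 after thinning, where almost no nuclei were classed (0.323% against 0.403%) and nothing can be read. Chromatin put 73.0% of the nuclei so named by RNA in the library labelled CKO into the class, against 17.7% of its AT2-like nuclei (78.3% and 23.6% in control nuclei), and the lower bound passed the value allowed by cluster names set wholly by RNA from other cells in 19 of 20 splits (20 after thinning). That speaks against this explanation for the whole excess without excluding it, because 1 split fell short of the criterion of every split. For a part of the excess this explanation cannot be told apart from an effect of the genotype, which was not tested. Promoters of AT1 identity genes did not follow the larger share. Over all alveolar nuclei they were lower in the library labelled CKO (median -0.32, percentile 1.1, 13 of 17 regions lower). Promoters of AT2 identity genes were lower too (percentile 1.58), so these promoters do not decide it.

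AT2 identity genes were higher in AT1-like nuclei of the library labelled CKO. The promoters of the list stood at percentile 30.9 there, with 7 regions, but in AT2-like nuclei, which make this RNA, promoters stood at 20.5 with RNA at 99.99, so promoter accessibility decides nothing about RNA from other cells. That explanation and an effect of the genotype cannot be told apart here.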

How the results depend on the processing

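No paired analysis was possible because each genotype has 1 library. Of 415 list percentiles under alternatives, 364 kept their side, 30 were no longer apart, 19 became so and 2 reversed; of 1062 log2 ratios of named genes, 832 stayed within their interval, 213 moved and 17 reversed. AP-1 subunits stayed at percentiles 0 to 0.01 in all 14 alternatives, as did immediate early genes. Some alternatives could not move a list's percentile, or only through the expression bins, because they shift the ratios of all genes alike. These were median-of-ratios scaling, all UMIs in the denominator, and ribosomal RNA-like genes left out of it. They are part of every count of alternatives given for a list, so those counts overstate how far the calls were checked. All causes below were not tested unless stated. The alternatives without a mitochondrial limit, without the highest doublet scores and without ribosomal RNA-like genes were chosen after seeing the data. The share of transitional-like or AT1-like nuclei was higher in the library labelled CKO in all 9 settings.

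With no filter on nuclei that share was 12.4% in the control library and 34.6% in the library labelled CKO, and the alveolar share of nuclei was 93.4% and 54.998%. Without the mitochondrial limit the first share was 17.1% and 35.8%. Centred within library it was 22.8% in the control library, and the alveolar share was 64.5% in the library labelled CKO. In the library labelled CKO the first share was 43.1% with doublets kept (that library had none called, so the change came through the 12 control nuclei and the clustering), 41.0% at Leiden resolution 0.3 and 53.6% at 1.2, and the alveolar share was 66.0% under the stricter filter and 65.9% without the top 8% of doublet scores. The median gene ratio was 0.56 with no filter, 0 under median of ratios by construction, and 0.31 without the 2 ribosomal RNA-like genes.

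With no filter and without the mitochondrial limit, percentiles were 22.6 and 11.4 for AT2 identity, 99.92 and 99.91 for the transitional list, 99.98 and 99.61 for p53 targets, and 0 and 0 for oxidative phosphorylation, which reversed. AT1 identity went to 95.5 under the other class makeup. Thinning to 1000 UMIs left 10 lists apart, from 16. With no filter, H2-DMb1 was at -0.22, Rpl10 at -0.014, Rtkn2 at 0.0021 and Cenpe at 0.040. Without the mitochondrial limit, H2-DMb1 was at -0.26, Rpl10 at -0.15, Rtkn2 at 0.21, Ager at -0.040 and Sftpd at -0.019. Under median of ratios, Cdkn1a was at -0.22, Fosl2 at -0.20, Mdm2 at -0.13, H2-DMb1 at -0.057, Rpl10 at -0.038 and Krt8 at -0.014. Under the other class makeup, Mdm2 was at -0.10 and Cenpe at 0.22.

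At 50% reciprocal overlap 84.2% of control peaks and 77.7% of peaks of the library labelled CKO were shared, and 97.0% and 52.5% among peaks with at least 50 counts. That cut left 40083 control peaks and 74103 of the library labelled CKO, whose kept nuclei held more peak counts (18192624 against 9979852). With fewer control peaks left to overlap, the 52.5% cannot be read as peaks particular to the library labelled CKO. The median accessibility ratio was 0.18 when scaled to promoter counts. The 4 motif alternatives were not run for want of a genome sequence, and minimum counts cannot move a single gene's ratio.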

Other observations

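YAP and TEAD targets were apart within AT2-like nuclei (median 0.79, percentile 97.9), where they were higher in the library labelled CKO. Lipid and surfactant synthesis genes, lower relative to like lists over all alveolar nuclei, were higher in transitional-like (0.70, percentile 99.93) and AT1-like nuclei (0.97, percentile 100). Airway epithelial markers had a higher median in AT1-like nuclei (2.23, percentile 100), but of 3 measured genes 1 was lower, and the median gene, Scgb1a1, stood at 1339 CPM in non-alveolar nuclei of the library labelled CKO. Interferon genes were lower relative to like lists in AT2-like (0.023, percentile 0.96), transitional-like (-0.27, percentile 0.05) and AT1-like nuclei (-0.26, percentile 0.09). Promoters of the JNK pathway were higher relative to like promoters in transitional-like nuclei (0.088, percentile 97.7), though 5 of 11 were lower. So were those of cAMP and CREB responsive genes in AT1-like nuclei (0.40, percentile 99.99), though 3 of 7 were lower. In AT2-like nuclei neither list was apart (-0.29 with 9 of 11 lower, percentile 23.5, and -0.22 with 11 of 14 lower, percentile 39.3). Promoters of senescence genes were lower in AT2-like nuclei (percentile 2.39, 7 of 10 lower).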
